A study of Mus musculus with 6 samples.

How the data were processed

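Droplet 3′ single-cell RNA libraries of mouse bone marrow from 4 MA9 and 2 HM leukaemias were analysed, 1 library per group. Per the labels' protocols, marrow was flushed, red cells were lysed and libraries were made with a Chromium 3′ kit given as v2. The deposited matrices hold raw UMI counts per gene and barcode, whole numbers with no normalisation, for barcodes of at least 500 UMIs. Per the file headers the MA9 matrices came from Cell Ranger 3.0.2, and per the submitters' processing notes all 6 libraries were aligned to mm10 with that version. The HM matrices name no software, list 32285 features against 31053 in MA9 and carry barcodes of 17 bases against 16. What the notes say of the HM files could therefore not be checked against their headers. Groups were taken from the labels alone. Gene coordinates came from GENCODE vM21 (GRCm38), and the identifiers of both named axis genes matched in all 6 libraries.

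Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. These were 94.8%, 90.9%, 94.8% and 87.9% of barcodes in the MA9 libraries labelled f/f PBS, Δ/Δ PBS, f/f AraC + Dox and Δ/Δ AraC + Dox, and 22.1% and 87.2% in the HM PBS and HM AraC + Dox libraries. Doublets were called with Scrublet in scanpy 1.11.5 and removed: 392, 330, 630, 374, 53 and 82 cells in the same order. Kept cells held 60230311, 86232861, 74788644, 96688619, 14735320 and 51604743 UMIs in the same order. The automatic Scrublet threshold marked 0%, 0.109% and 0.0855% of cells in the library labelled MA9 Δ/Δ PBS and in both HM libraries. There the mean threshold of the other 3 libraries, 0.184, was used instead, a choice made after seeing the data.

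UMIs were summed over the kept cells of a library and scaled to counts per 1e6 UMIs (CPM). A log2 ratio compares the CPM of the first library with that of the second, with an exact Clopper-Pearson 95% interval conditional on the sum of both counts. A gene with 0 UMIs in 1 library was set to a floor of 3 counts in that library, and its fold is given as "at least". Genes at 20 CPM or more in either library were compared, and a difference of at least 2-fold was counted as a rule of size, not as a test. Cells are not replicates, so no p-value, standard error or count of significant genes was computed from cells. Intervals and floors cover counting error only.

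For each of 33 gene lists the members at 5 CPM or more in either library were summarised by their median log2 ratio and by the number at least 1.25-fold higher or lower. The interval in brackets after a list median comes from 2000 draws of the members. The percentile of the median was taken among 10000 random lists of the same size matched in 20 bins of expression. Lists with fewer than 3 measured members were not read as lists. The difference between the pairs labelled as chemotherapy was taken per member measured in both. Contrasts that share no library were compared by Pearson and Spearman correlation across genes, with the number past 2-fold in both set against the product of the separate shares.

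Named genes follow a rule: Ptpn6 and Pfkp always, and in each comparison the 10 largest and 10 smallest log2 ratios among genes at 20 CPM or more in either library whose interval excludes 0. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and gene models known only by a code were counted but not named among these. For each list described, up to 4 members at 20 CPM or more with the largest absolute log2 ratio could be named, and for progenitor-like against neutrophil-like and monocyte-like cells up to 4 with the largest mean difference among those of 1 sign in every library. Jchain had been left out of naming in a first run, and this was undone to follow the rule as written. A result withheld for evaluation is not reported here.

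The 4 MA9 libraries and the 2 HM libraries were clustered apart: 2000 variable genes chosen within each library, genes of the lists left out unless they are cell type markers, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1, without batch correction. Clusters were named from 18 marker lists as "-like" classes where at least 3 markers were 2-fold higher in the cluster and another type did not lead its 10 top genes. This naming rule, and the merging of immature and mature neutrophil markers into 1 class, were settled after seeing the clusters. Shares of classes carry exact binomial 95% intervals. Ratios within a class were taken where both libraries held at least 50 of its cells.

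Stem and progenitor-like cells were compared with neutrophil-like and monocyte-like cells within each library, and the 1 value per library and list was tested by a two-sided exact sign-flip permutation test with Benjamini-Hochberg adjustment. The HM PBS library was left out for its 12 progenitor-like cells, so 5 libraries and 32 sign patterns were used in place of the planned 64, and the smallest p is 0.0625. A first run used lists picked by hand. It was replaced, after its output had been seen, by every list with at least 3 members that are not markers and reach 20 CPM in every library used, which gave 28 lists. In neither run could a list pass a threshold of 0.05.

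Alternatives changed 1 choice at a time: no cell filter, a stricter filter (1000 genes, 5.0% mitochondrial UMIs), doublets kept, median-of-ratios or TMM factors (edgeR 4.0.16 in R 4.3.3), equal weight per cell, thinning to 2000 UMIs, a minimum of 50 CPM or none, and Leiden resolutions of 0.5 and 1.5. A setting with the labels of the MA9 libraries in doubt exchanged was computed and seen, and then replaced by the 1 pair of MA9 libraries whose labels Ptpn6 does not go against. Groups, gene lists, marker lists, the naming rule for genes, the rule of size and all alternatives but those stated as chosen later were fixed before the data were examined.

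The calculation was tested on simulated data for each comparison, in which 200 genes were changed. In the PBS, AraC + Dox, f/f, Δ/Δ and HM pairs 5796, 5710, 5635, 5754 and 4665 genes were compared. Of 67 genes changed 3-fold and 66 changed 4-fold 100% were counted as at least 2-fold apart in each of the 5, and of 67 changed 1.5-fold 0%. No unchanged gene was counted. The intervals held the simulated ratio for 95.2%, 95.1%, 95.1%, 94.1% and 95.4% of genes in the same order, and a list shifted 1.5-fold reached percentile 100. Of lists that were not shifted, 6%, 5%, 4%, 5% and 4% lay outside percentiles 2.5 to 97.5. The simulation draws counts only and holds no difference between animals. Sequence reads were not used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.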

Results

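Single-cell transcriptomes of bone marrow from mice with acute myeloid leukaemia were collected as 6 droplet libraries. The leukaemias were driven by MLL-AF9 (MA9, 4 libraries) or by Hoxa9 and Meis1 (HM, 2 libraries). The MA9 libraries cross the floxed, undeleted state (f/f) or the deletion (Δ/Δ) of Shp-1, a tyrosine phosphatase encoded by Ptpn6, with PBS or AraC + Dox chemotherapy. Both HM libraries are f/f, 1 given PBS and 1 given AraC + Dox. Each group held 1 library, so differences between groups have no check against replicates, and no test between groups was made. Every interval on a ratio or a level below is an exact 95% interval for counting error only.

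The deposited matrices held 9090 barcodes and 65640410 UMIs in the library labelled MA9 f/f PBS. They held 10380 barcodes and 91471090 UMIs in that labelled MA9 Δ/Δ PBS, and 10281 and 82506203 in that labelled MA9 f/f AraC + Dox. The library labelled MA9 Δ/Δ AraC + Dox held 10748 barcodes and 105272403 UMIs. The HM libraries held 12474 barcodes with 29347365 UMIs (PBS) and 5364 barcodes with 54025160 UMIs (AraC + Dox). After filtering, 8222, 9101, 9120, 9072, 2702 and 4594 cells were kept in the same order, with median depths of 6558, 7401, 7728.5, 9871, 3975 and 6733.5 UMIs. In the HM PBS library 74.7% of barcodes lay over the limit of 10% mitochondrial UMIs, against 1.83% to 8.33% in the other libraries.

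Ptpn6 (ENSMUSG00000004266; GRCm38 chromosome 6, 124720707 to 124738714, minus strand) stood at 186 CPM (counts per 1e6 UMIs; 182 to 189) in the library labelled MA9 f/f PBS and at 172 CPM (169 to 174) in that labelled MA9 Δ/Δ PBS. It stood at 57.7 CPM (56.0 to 59.5) in the library labelled MA9 f/f AraC + Dox and at 43.5 CPM (42.2 to 44.8) in that labelled MA9 Δ/Δ AraC + Dox. The HM libraries held 135 CPM (129 to 141, PBS) and 113 CPM (110 to 116, AraC + Dox). Ptpn6 therefore went against 2 labels: it was near the f/f PBS level in a library labelled Δ/Δ and 3.22-fold below that level in a library labelled f/f. Which exons were deleted is not given in the sources used here, and a 3′ tag outside the deleted part would check nothing about a deletion. The MA9 comparisons below are named by the labels, of which 2 are in doubt. If those 2 were exchanged, no direction would turn, but the factor compared would change. The pairs labelled as deletion would then compare AraC + Dox with PBS, and those labelled as chemotherapy Δ/Δ with f/f.

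Pfkp, the platelet-type phosphofructokinase that commits sugar to glycolysis (ENSMUSG00000021196; GRCm38 chromosome 13, 6579768 to 6648777, minus strand), was 31.5 CPM (30.1 to 33.0) in the library labelled MA9 f/f PBS and 44.9 CPM (43.5 to 46.4) in that labelled MA9 Δ/Δ PBS. With AraC + Dox it was 39.2 CPM (37.8 to 40.6) in the library labelled f/f and 63.1 CPM (61.5 to 64.7) in that labelled Δ/Δ. In HM it was 36.8 CPM (33.8 to 40.0) with PBS and 33.6 CPM (32.0 to 35.2) with AraC + Dox.

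**Figure D1:**
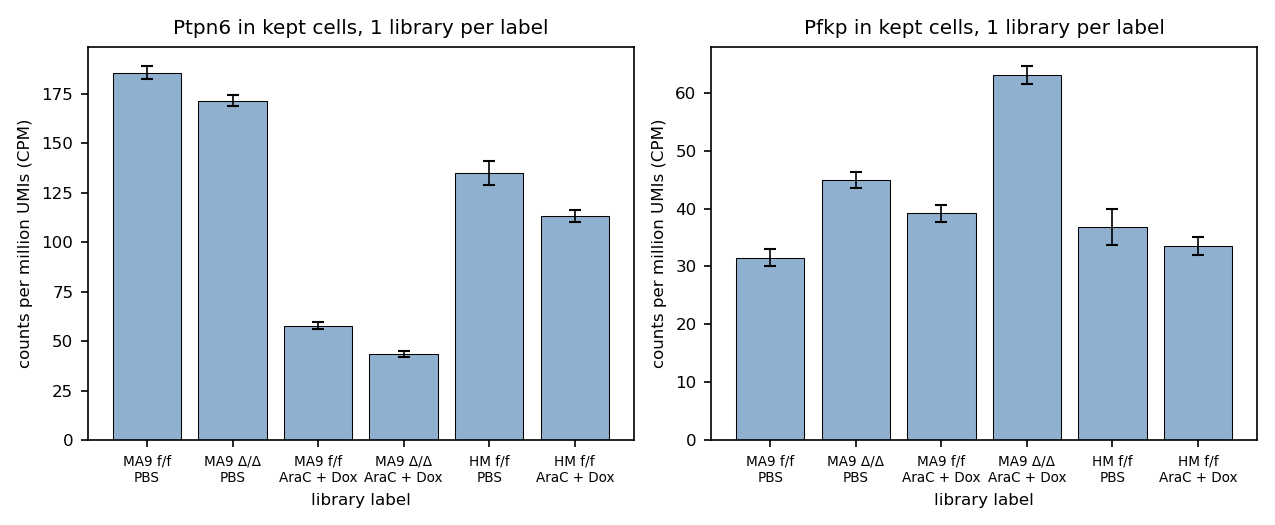
Ptpn6 and Pfkp in kept cells (bars, CPM, 1 library per label; error bars, exact 95% counting intervals). Ptpn6 was 57.7 and 43.5 CPM in the MA9 libraries labelled AraC + Dox and between 113 and 186 CPM in the other 4; Pfkp was highest, at 63.1 CPM, in the library labelled MA9 Δ/Δ AraC + Dox.

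Ptpn6 differed between classes of cells as well as between libraries. Between the libraries labelled f/f AraC + Dox and f/f PBS its log2 ratio was -1.84 (-1.95 to -1.73) in monocyte-like cells, -1.69 (-1.76 to -1.62) in neutrophil-like cells and -1.68 (-2.15 to -1.25) in stem and progenitor-like cells. In T cell-like cells it was -0.18 (-1.35 to 0.97; 51 and 64 cells), so a difference was not detectable at this depth. Between the libraries labelled Δ/Δ AraC + Dox and Δ/Δ PBS it was -3.19 (-3.80 to -2.65) in conventional dendritic cell-like cells, -2.28 (-2.39 to -2.16) in monocyte-like cells and -1.39 (-1.67 to -1.13) in stem and progenitor-like cells, of which cluster 13 held 1001 of 1866 with PBS and cluster 6 171 of 257 with AraC + Dox. In the same pair it was -0.10 (-0.37 to 0.17) in B cell-like cells (434 and 392 cells) and -0.01 (-0.42 to 0.40) in T cell-like cells (223 and 352 cells).

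**Figure D2:**
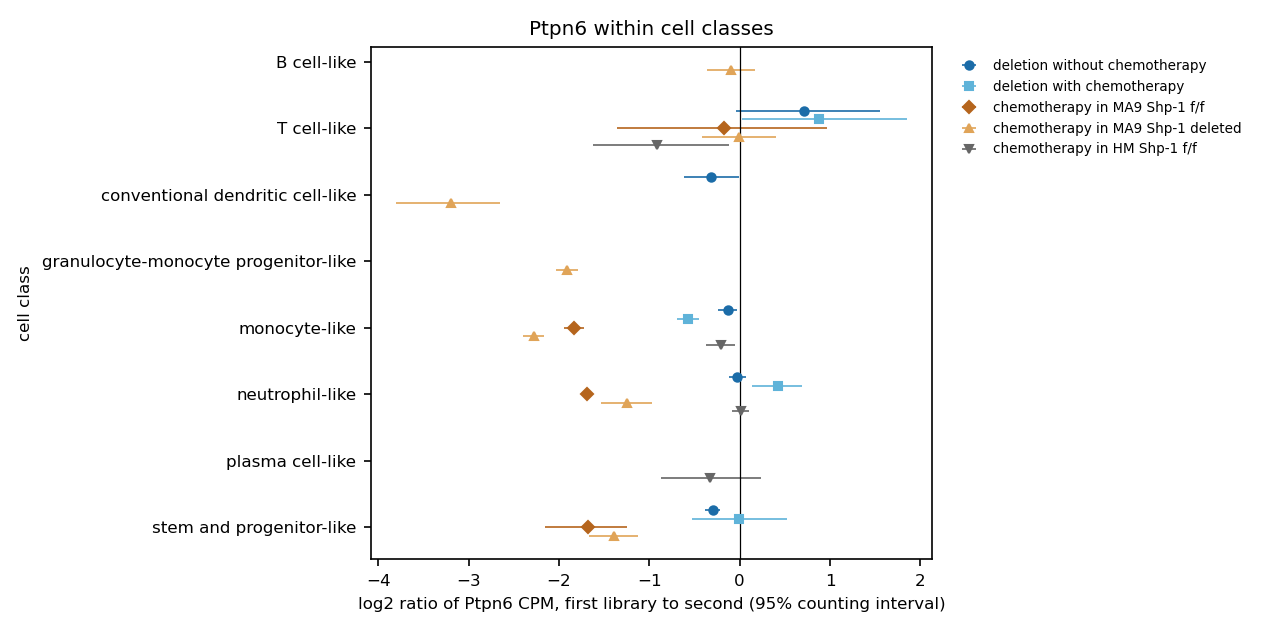
Log2 ratio of Ptpn6 CPM within each cell class held by at least 50 cells in both libraries of a comparison (points; bars, exact 95% counting intervals), by comparison as labelled. In the pairs labelled as chemotherapy in MA9 the myeloid and progenitor classes lay between -3.19 and -1.25, and the B cell-like and T cell-like classes between -0.18 and -0.01.

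Neutrophil-like cells were the largest named class in the MA9 library labelled f/f PBS (54.8% of kept cells, exact binomial 95% interval 53.7 to 55.9) and in that labelled f/f AraC + Dox (48.4%, 47.4 to 49.4). They were 11.4% (10.7 to 12.1) and 3.40% (3.03 to 3.79) in the libraries labelled Δ/Δ PBS and Δ/Δ AraC + Dox. Stem and progenitor-like cells made up 12.0% (11.3 to 12.8) of the library labelled f/f PBS, 20.5% (19.7 to 21.3) of that labelled Δ/Δ PBS, 1.35% (1.12 to 1.61) of that labelled f/f AraC + Dox and 2.83% (2.5 to 3.20) of that labelled Δ/Δ AraC + Dox. Granulocyte-monocyte progenitor-like cells, the precursors of both myeloid lines, reached 31.1% (30.2 to 32.1) in the library labelled Δ/Δ AraC + Dox against 0.146% to 4.09% in the other MA9 libraries. B cell-like cells were 4.31% and 4.78% of the libraries labelled Δ/Δ and 0.426% and 0.406% of those labelled f/f, and T cell-like cells 3.87% and 2.46% against 0.778% and 0.559%. In the libraries labelled f/f PBS, Δ/Δ PBS, f/f AraC + Dox and Δ/Δ AraC + Dox, monocyte-like cells were 12.9%, 7.63%, 25.5% and 24.97%, macrophage-like cells 0.207%, 1.03%, 0.110% and 0.408%, and erythroid-like cells 0.134%, 0.0330%, 2.69% and 0.0331%. These 3 shares depended on the clustering: at a Leiden resolution of 0.5 they were, in the same order, 15.4%, 15.5%, 25.7% and 23.4%, then 0.778%, 1.70%, 0.570% and 1.41%, and 0.401%, 0.143%, 0.296% and 0.441%. At a resolution of 1 the erythroid-like class was cluster 22 alone, named from 4 haemoglobin genes, with 3 neutrophil markers next. Its median depth was 0.148 times that of the library. Unnamed cluster 23 had 20 erythroid markers, mixed with other types, and 37, 55, 36 and 63 cells in the same order. The erythroid-like share may therefore not count erythroid cells. Cells in clusters without a name by the fixed rule made up 17.5% to 36.7% of the MA9 libraries.

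In HM, T cell-like cells were 1.92% (1.44 to 2.52) with PBS and 18.1% (17.03 to 19.3) with AraC + Dox. All HM shares are of cells past the filter, which passed 22.1% of PBS and 87.2% of AraC + Dox barcodes. The barcodes dropped from PBS differed in expression from those kept, and the intervals do not cover this selection. Mast cell and basophil-like cells were 0 of 2702 with PBS (exact binomial 95% upper limit 0.136%) and 2.00% with AraC + Dox. Neutrophil-like cells were 85.8% (84.5 to 87.1) with PBS and 56.3% (54.8 to 57.7) with AraC + Dox, and stem and progenitor-like cells 0.444% (12 cells) and 2.92% (134 cells). Monocyte-like cells were 7.29% with PBS and 7.38% with AraC + Dox, plasma cell-like cells 3.03% and 3.77%, granulocyte-monocyte progenitor-like cells 0.999% and 2.44%, and cells of unnamed clusters 0.407% and 3.94%. At a Leiden resolution of 0.5 these HM shares were 9.55% and 4.92% for monocyte-like, 0.148% and 0.805% for plasma cell-like and 1.89% and 10.7% for granulocyte-monocyte progenitor-like cells. With doublets kept, plasma cell-like cells were 2.90% and 1.13%, so no direction is read from the monocyte-like and plasma cell-like shares. Different clusters held most neutrophil-like cells of the HM libraries: cluster 0 held 1083 PBS and 11 AraC + Dox cells, and cluster 1 held 4 and 1072. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. In MA9, monocyte-like cluster 7 held 1584 cells of the library labelled Δ/Δ AraC + Dox and 8 of that labelled f/f PBS, and neutrophil-like cluster 0 held 11 and 1479. The granulocyte-monocyte progenitor-like share depended on the clustering: at a Leiden resolution of 0.5 it was 10.1% in the library labelled f/f PBS, 13.9% in that labelled f/f AraC + Dox and 6.59% in that labelled Δ/Δ PBS. The stem and progenitor-like share at that resolution was 40.2% in the library labelled Δ/Δ PBS and 5.26% in that labelled Δ/Δ AraC + Dox, where a resolution of 1.5 gave 4.33%, with 7.69% neutrophil-like cells.

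**Figure D3:**
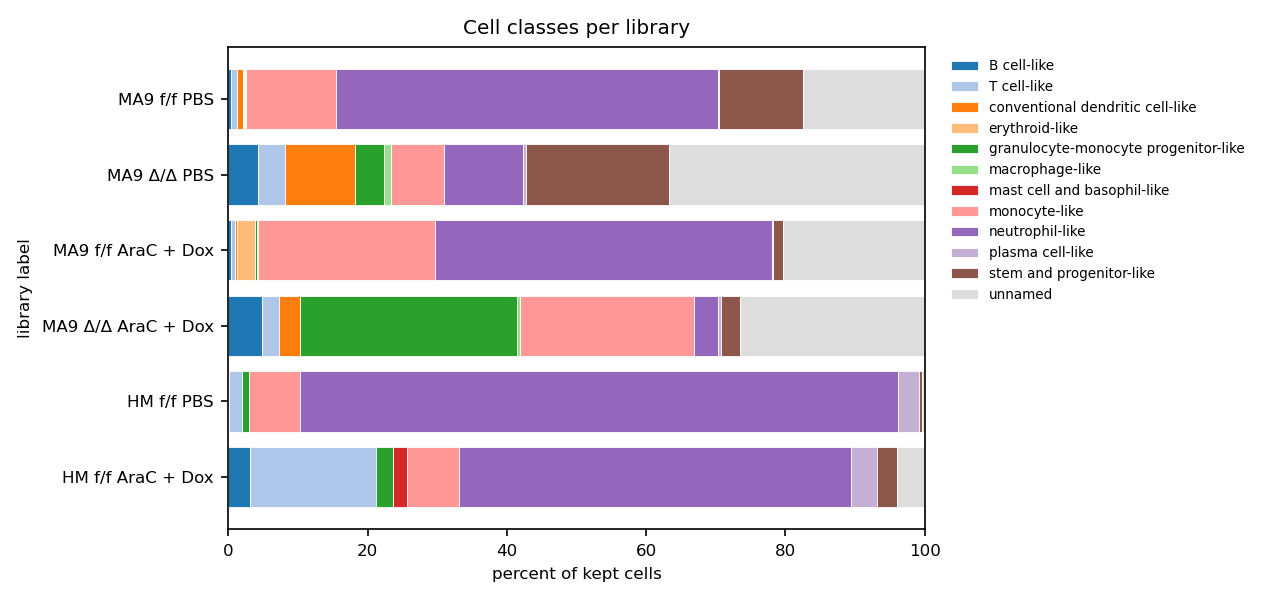
Share of kept cells (percent, stacked bars) in each cell class, 1 library per label. Neutrophil-like cells were 54.8% and 48.4% of the MA9 libraries labelled f/f and 11.4% and 3.40% of those labelled Δ/Δ, and T cell-like cells were 18.1% of the HM library given AraC + Dox against 1.92% with PBS. The cell filter passed 87.2% and 22.1% of the barcodes of these HM libraries.

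As labelled, the first comparison asks what Shp-1 loss alone does to the leukaemia. It sets the library labelled Δ/Δ PBS against that labelled f/f PBS (the PBS pair). Genes of neutrophil granules were far lower in the library labelled Δ/Δ: Camp, an antimicrobial peptide, was 14.2-fold lower (log2 ratio -3.83, -3.84 to -3.82), Ltf (lactoferrin) 13.5-fold and S100a9 7.61-fold lower. Sox4, a transcription factor of progenitors, was 7.02-fold higher (2.81, 2.73 to 2.89), the receptor kinase Flt3 had a log2 ratio of 2.24 (2.14 to 2.34) and Cd34 1.66 (1.59 to 1.73), while MLL and HOX leukaemia genes as a list had 14 of 28 members higher and 9 lower. Col1a2 and Col1a1, collagen chains made by stroma, were 38.9-fold and 35.0-fold higher at 34.2 and 32.5 CPM. Sparc was 18.5-fold and Cxcl12, a niche chemokine, 12.4-fold higher. With doublets kept, 36 mesenchymal stromal-like cells were found in the library labelled Δ/Δ and 3 in that labelled f/f. No such class was named with doublets removed. Ly6k (20.4-fold), Ifitm1 (14.1-fold), the cyclin Ccnd1 (11.1-fold), Ly6a (7.23-fold) and Xlr (6.95-fold) completed the 10 genes highest in the library labelled Δ/Δ. Orm1 (15.6-fold), the carbonic anhydrase Car2 (15.3-fold), Ngp (12.2-fold), Mogat2 (9.36-fold), Itgb2l (8.41-fold), Fcnb (7.86-fold) and Plbd1 (7.16-fold) completed the 10 lowest.

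Granule protein genes as a list had a median log2 ratio of -2.38 in the PBS pair, with 15 of 20 measured members lower and 4 higher, beside neutrophil-like shares of 11.4% and 54.8%. Genes of MYC activity and ribosome biogenesis had a median of 0.99 (0.87 to 1.11 by resampling of members) and 24 of 24 members higher, led by Srm (1.40), Gnl3 (1.37) and Nolc1 (1.34). The same list had medians of 0.67 in stem and progenitor-like cells and 1.14 in monocyte-like cells of the pair, but different clusters held most of these cells. Cluster 7 held 238 and 8 of the monocyte-like cells and cluster 9 33 and 482, and cluster 13 held 1001 and 184 of the progenitor-like cells. Antigen presentation by MHC class I had 21 of 22 members higher (median 0.83), among them H2-Q7 (1.98), H2-K1 (1.21) and the immunoproteasome subunit Psmb8 (1.18). Interferon response genes had 27 of 30 higher (0.97), among them Ly6a (2.85), Gbp7 (1.37) and Gbp3 (1.32), but within classes the median was 0.07 in monocyte-like, 0.17 in stem and progenitor-like and 1.49 in neutrophil-like cells. Among p53 targets 12 of 22 were higher and 3 lower (0.39), with the cell cycle inhibitor Cdkn1a at 1.64 (1.57 to 1.71), Ccng1 at 1.05 and the death effector Bax at 0.97. The tricarboxylic acid cycle had 14 of 22 members higher (0.41), such as Idh2 (0.98) and Idh3a (0.73). Nuclear genes of oxidative phosphorylation had 28 of 73 higher and 0 lower (0.28), such as Cycs (0.81) and Atp5g1 (0.68), and fatty acid oxidation 10 of 20 higher (0.32), such as Hadh (0.99). MHC class I, p53 and the metabolic lists were summed over all kept cells, so their values hold the difference in cell mix. MHC class I (mean 0.51) and fatty acid oxidation (0.34) were higher in progenitor-like than in neutrophil-like and monocyte-like cells in 5 of 5 libraries. The tricarboxylic acid cycle was so in 4 of 5 (0.29), and p53 targets (0.29) and oxidative phosphorylation (0.19) in 3 of 5. The part of cell mix was not tested.

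Glycolysis went both ways in the PBS pair, with 6 members higher and 7 lower of 22 and a median of -0.02 (-0.35 to 0.27), at percentile 3.52 of random lists of like expression, whose median was 0.18. The neuronal-type glucose transporter Slc2a3 was -2.23 (-2.34 to -2.12), Gpi1 -0.71 and the lactate exporter Slc16a3 -0.68, against 0.51 (0.43 to 0.59) for Pfkp. Inhibitory ligands for immune cells were lower in 6 of 12 (-0.42), with Ceacam1 at -1.92 and Vsir, which encodes the checkpoint VISTA, at -1.54. Of 6146 genes compared, 235 were at least 2-fold higher and 239 at least 2-fold lower in the library labelled Δ/Δ. Median-of-ratios scaling shifts all ratios of this pair by -0.17 and gives 140 higher and 339 lower, and the oxidative phosphorylation median then is 0.11. Reading this pair as deletion rests on a label in doubt. Ptpn6 was -0.12 (-0.15 to -0.08) in the library labelled Δ/Δ relative to that labelled f/f PBS, and -0.29 with median-of-ratios scaling.

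As labelled, the second comparison asks what Shp-1 loss does under chemotherapy. It sets the library labelled Δ/Δ AraC + Dox against that labelled f/f AraC + Dox (the AraC + Dox pair). Gdf3, a growth factor of the TGF-beta family, was 144-fold higher in the library labelled Δ/Δ (log2 ratio 7.17, 6.62 to 7.77). Phgdh, which opens serine synthesis, was 11.6-fold higher (3.54, 3.43 to 3.65), and Clec10a, a lectin of macrophages and dendritic cells, 10.6-fold. Stfa1, a myeloid cysteine protease inhibitor, was 58.0-fold lower (-5.86, -5.90 to -5.82), with Stfa2l1 at -4.49, Stfa3 at -4.41 and Stfa2 at -4.24, and Camp was 20.8-fold lower. Hist1h2ap (4.99), Hmgn3 (4.84), Vill (4.36), Hist2h2aa1 (3.21), Serpina3g (3.12), Chd3 (3.11) and Polr2l (3.09) completed the 10 genes highest in the library labelled Δ/Δ. Orm1 (-4.62), Ltf (-3.70), Chil3 (-3.42), Clec4b2 (-3.38) and Dapk2 (-3.38) completed the 10 lowest.

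Ribosome biogenesis genes were higher in 23 of 24 members in the AraC + Dox pair (median 1.34, 1.24 to 1.38), with Wdr43 at 2.08, Srm at 1.83 and Cad, which starts pyrimidine synthesis, at 1.71. Within monocyte-like cells the median of this list was 1.5, and within neutrophil-like cells, 3.40% and 48.4% of the libraries, it was -0.70. Different clusters held most of both classes: cluster 7 held 1584 and 16 of the monocyte-like cells, cluster 9 held 5 and 1033, and neutrophil-like cluster 0 held 11 and 1696. Genes of MHC class II had 8 of 11 members higher (1.96), with H2-Eb1 at 2.26, H2-Aa at 2.11 and Cd74 at 1.96. Conventional dendritic cell-like shares were 3.08% and 0.208%. These same genes helped to name that class, cluster 14, so its share is no separate evidence. The cluster had 6 dendritic cell markers and also 6 of stem and progenitor cells. MHC class I had 19 of 22 higher (0.61), with H2-Q6 at 2.40 and H2-Q7 at 1.93. Mitochondrially encoded genes had 9 of 13 higher (0.72), among them mt-Nd4l (2.42), mt-Nd3 (1.73) and mt-Co1 (1.33). The median mitochondrial share of kept cells was 3.65% in the library labelled Δ/Δ and 2.71% in that labelled f/f. Barcodes over the mitochondrial limit were 8.30% and 1.95%. Nuclear oxidative phosphorylation had 30 of 73 higher and 2 lower (0.25), among them Atp5k (2.24) and Ndufa3 (1.13). S phase genes had 15 of 28 higher and 0 lower (0.43), and p53 targets 10 of 22 higher and 3 lower (0.24), with Cdkn1a at 1.28 (1.22 to 1.34). The MHC, oxidative phosphorylation, S phase and p53 values here are sums over libraries of different cell mix, whose part was not tested.

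Glycolysis had 7 members higher and 6 lower of 22 in the AraC + Dox pair (0.12, -0.15 to 0.34; percentile 65.8 of random lists). The lactate and pyruvate carrier Slc16a1 was 1.99 (1.84 to 2.14), enolase Eno1 1.92 (1.88 to 1.96), the hexokinase Hk2 1.20 and Pfkp 0.69 (0.62 to 0.75), while Slc2a3 was -1.25. Granule proteins were lower in 14 of 20 (-1.74), beside the neutrophil-like shares above. Of 6066 genes compared, 333 were at least 2-fold higher and 287 lower in the library labelled Δ/Δ (270 and 347 with median-of-ratios scaling). The label f/f is in doubt here: Ptpn6 was -0.41 (-0.47 to -0.35) in this pair, and 0.03 when each cell was given equal weight.

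As labelled, the third comparison asks what AraC + Dox does to MA9 leukaemia with Shp-1 present. It sets the library labelled f/f AraC + Dox against that labelled f/f PBS (the f/f pair). Of 5775 genes, 22 were at least 2-fold higher and 54 at least 2-fold lower, fewer than in any of the other 4 comparisons. Cd34, a surface protein of progenitors, was 5.85-fold lower (log2 ratio -2.55, -2.71 to -2.39), Pbx3, a HOX cofactor, 4.81-fold (-2.27, -2.38 to -2.15), and Sox4 had a log2 ratio of -1.51. Ptpn6 was 3.22-fold lower (-1.69, -1.74 to -1.64), although this library is labelled f/f. Ly6k was 11.8-fold higher (3.56), the chromatin organiser Satb1 3.66-fold (1.87) and the kinase Pim1 2.42-fold (1.28). Vill was 17.4-fold lower (-4.12), Adgrl4 13.3-fold lower, and the adhesion molecule Vcam1 was at -1.76. Also among the 10 highest were Myl10 (1.96), Col19a1 (1.71), Upb1 (1.62), Lmo1 (1.38), S100a4 (1.31), Kctd14 (1.20) and Gng10 (1.20). Also among the 10 lowest were Tespa1 (-2.86), Hist1h2ap (-2.52), Tsc22d1 (-2.21), Fnbp1l (-1.96) and the iron exporter Slc40a1 (-1.76).

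The list of MLL and HOX leukaemia genes had 9 of 28 members lower, 1 higher and 18 between in the f/f pair (median -0.14), beside stem and progenitor-like shares of 1.35% and 12.0%. MHC class II genes were lower in 6 of 9 (-0.75, -0.86 to 0.29), with H2-Eb1 at -0.86, H2-Ab1 at -0.84 and Cd74 at -0.56. Conventional dendritic cell-like shares were 0.208% and 0.851%, a class that these same genes helped to name. Fatty acid and cholesterol synthesis had 6 of 18 members higher and 0 lower (0.20), with farnesyl diphosphate synthase Fdps at 1.09 and Scd2 at 0.80. Glycolysis had a median of 0.11 (-0.01 to 0.17; percentile 88.5 of random lists) and a mean of -0.02, with 2 of 21 higher and 3 lower: Hk2 was -1.38 (-1.44 to -1.32), Slc2a3 -0.61, Eno1 -0.57 and Pfkp 0.31 (0.23 to 0.40). Oxidative phosphorylation had 3 of 73 higher and 3 lower (0.13), and mitochondrially encoded genes 5 of 13 lower (-0.20), with mt-Nd4l at -1.47. The p53 targets were near 0 (-0.01; 1 of 20 higher, 3 lower), with Cdkn1a at 0.36 (0.28 to 0.45) and Bax at 0.24. The interferon response median was 0.05 (4 of 23 higher, 0 lower), and granule proteins were lower in 9 of 20 (-0.23), such as Mmp9 (-1.30).

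As labelled, the fourth comparison asks the same with Shp-1 deleted. It sets the library labelled Δ/Δ AraC + Dox against that labelled Δ/Δ PBS (the Δ/Δ pair). Cpa3, a mast cell protease, was 76.9-fold lower (log2 ratio -6.26, -6.59 to -5.96), and Prg2, an eosinophil granule protein, 17.4-fold lower. The niche factor Angpt1 was 11.1-fold lower (-3.47, -3.63 to -3.33) and Pbx3 10.2-fold (-3.35, -3.46 to -3.24), with Cd34 at -2.39 and Flt3 at -1.80. Cpa3 and Angpt1 are top genes of stem and progenitor-like cluster 6, with 171 cells with AraC + Dox and 865 with PBS. No mast cell class was named in MA9. Ptpn6 was 3.95-fold lower (-1.98, -2.03 to -1.93), although both libraries are labelled Δ/Δ. Hist1h2ap was 10.6-fold higher (3.41) and Gdf3 5.38-fold higher (2.43). Also among the 10 highest were Krtcap3 (2.54), Emp1 (2.51), Mgam (2.40), Tmem108 (2.21), the platelet chemokine Pf4 (2.11), Lipg (2.10), Cdk5rap1 (1.92) and Hmgn3 (1.86). Also among the 10 lowest were Xlr (-4.03), Adgrl4 (-3.70), Ddx4 (-3.34), Stfa1 (-2.89), Stfa3 (-2.83) and Stfa2 (-2.61).

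Glycolysis genes were higher in 9 of 22 members and lower in 2 in the Δ/Δ pair (median 0.32, 0.17 to 0.34), led by Eno1 (1.36, 1.33 to 1.39), Slc16a1 (1.01) and Pfkp (0.49, 0.43 to 0.55). All of 10000 random lists of like expression had a lower median, but glycolysis did not stand alone in this. The same held for S phase, ribosome biogenesis, granule protein and haemoglobin genes, and oxidative phosphorylation lay at percentile 99.87. Within stem and progenitor-like cells the glycolysis median was 0.09. Interferon response genes were lower in 20 of 31 (-0.47, -0.59 to -0.32), with Irf1 at -0.78, Irf7 at -0.69 and Xaf1 at -0.68. The list of MLL and HOX leukaemia genes had 13 of 27 lower, 1 higher and 13 between (-0.30), beside stem and progenitor-like shares of 2.83% and 20.5%. S phase genes had 10 of 28 higher and 0 lower (0.23), with Rrm2, a subunit of ribonucleotide reductase, at 1.03. Ribosome biogenesis genes had 10 of 24 higher and 0 lower (0.26), but in neutrophil-like cells 13 of 14 lower (-0.76) and in stem and progenitor-like cells a median of 0.06. Oxidative phosphorylation had 6 of 73 higher and 1 lower (0.09, and 0.19 with median-of-ratios scaling), and p53 targets 4 higher and 8 lower of 21 (-0.09, and 0.02 with median-of-ratios scaling). Immediate early and heat shock genes were higher in 9 of 21 and lower in 0 (0.24), led by Jun (1.12) and Egr1 (1.11). MHC class II had 3 higher and 3 lower of 11 (median 0.14, mean -0.08), with H2-Ob at -1.17. Of 6017 genes compared, 47 were at least 2-fold higher and 93 lower (59 and 77 with median-of-ratios scaling).

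The fifth comparison asks what AraC + Dox does in the HM model and sets the HM library given AraC + Dox against that given PBS (the HM pair). Interferon-induced genes were far lower with AraC + Dox: Ifit2 by 18.1-fold (log2 ratio -4.18, -4.35 to -4.00), Ifit3 by 13.7-fold (-3.78, -3.87 to -3.69) and Isg15, a ubiquitin-like modifier, by 8.93-fold (-3.16, -3.20 to -3.11). Prss34, Mcpt8 and Cpa3, proteases of mast cells and basophils, were higher by 457-fold (8.84, 8.03 to 9.79), 163-fold (7.35, 6.77 to 7.99) and 74.6-fold, beside the mast cell and basophil-like share of 2.00%. Ccr7, a homing receptor of lymphocytes, and Fcer1a, the IgE receptor chain, had 0 UMIs with PBS and were at least 118-fold and at least 104-fold higher against a floor of 3 counts. The acute phase gene Saa3 was 26.8-fold lower (-4.75). Also among the 10 highest were Mt2 (5.41), Ctla2a (5.06), Prg2 (5.03), Id3 (4.77) and Sh2d2a (4.68). Also among the 10 lowest were Ifit1bl1 (-4.74), Tpm3-rs7 (-4.11), Ifit3b (-3.97), H2-T24 (-3.45), Usp18 (-3.14) and Ifit1bl2 (-3.07).

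Interferon response genes were lower in 31 of 33 members in the HM pair (median -1.94, -2.35 to -1.71). They were also lower within each class compared: 28 of 29 in neutrophil-like cells (-1.88), 27 of 29 in monocyte-like cells (-1.99), 33 of 33 in T cell-like cells (-2.51; cluster 14 held 31 of 52 with PBS and cluster 2 713 of 833 with AraC + Dox) and 27 of 30 in plasma cell-like cells (-2.18). Of the plasma cell-like cells 78 of 82 with PBS and 136 of 173 with AraC + Dox lay in cluster 10. That cluster was named from only 3 markers. Ribosomal protein genes were higher in 46 of 46 (1.24, 1.13 to 1.33), with Rpl12 at 1.96 and Rpl14 at 1.69, and ribosome biogenesis genes in 20 of 24 (0.93), with Odc1 at 1.79. The ribosome biogenesis median turned to -0.037 with all deposited barcodes kept. Oxidative phosphorylation was higher in 60 of 73 and lower in 0 (0.73, 0.63 to 0.79), with Uqcrc2 at 1.38 and Atp5b at 1.22 (median 1.17 with all deposited barcodes), but its median was 0.22 within neutrophil-like cells and 0.01 within T cell-like cells. The tricarboxylic acid cycle had 20 of 22 higher (0.70), with Suclg2 at 1.79 and Idh3a at 1.42. Mitochondrially encoded genes were lower in 7 of 13 (-0.42), with mt-Co1 at -0.82, in a pair whose PBS library lost 74.7% of barcodes at the mitochondrial limit.

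MHC class II genes were higher in 9 of 11 in the HM pair (2.59, 0.65 to 3.59), with H2-Aa at 3.97 (3.75 to 4.21) and Cd74 at 3.34, beside B cell-like shares of 3.13% and 0.0740% and unnamed cluster 13, which genes of this list lead, with 152 and 4 cells. Effector genes of T and NK cells were higher in 4 of 6 (2.05), led by granzyme B, Gzmb, at 4.33 (3.80 to 4.91), beside T cell-like shares of 18.1% and 1.92%. Among p53 targets 11 of 21 were higher and 4 lower (0.50, and -0.01 with all deposited barcodes), with Bbc3, which encodes PUMA, at 1.87 and Cdkn1a at 1.04 (0.96 to 1.12). Glycolysis had 4 higher and 8 lower of 21 (-0.13, -0.46 to 0.23, percentile 8.79 of random lists, and 0.36 with all deposited barcodes), with Pfkfb4 at -1.47, Hk2 at -1.34, Hk3 at -1.25 and Pfkp at -0.13 (-0.27 to 0.01; -0.56 with all deposited barcodes). Drug transport and nucleoside metabolism genes had 3 higher and 5 lower of 12 (0.02). Deoxycytidine kinase, Dck, which activates AraC, was -1.30 (-1.42 to -1.19), and Samhd1, which breaks down its active form, -1.07. Ptpn6 was -0.25 (-0.33 to -0.18), and 0.16 with all deposited barcodes. Of 5132 genes compared, 657 were at least 2-fold higher and 545 lower with AraC + Dox (530 and 629 with median-of-ratios scaling).

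**Figure D4:**
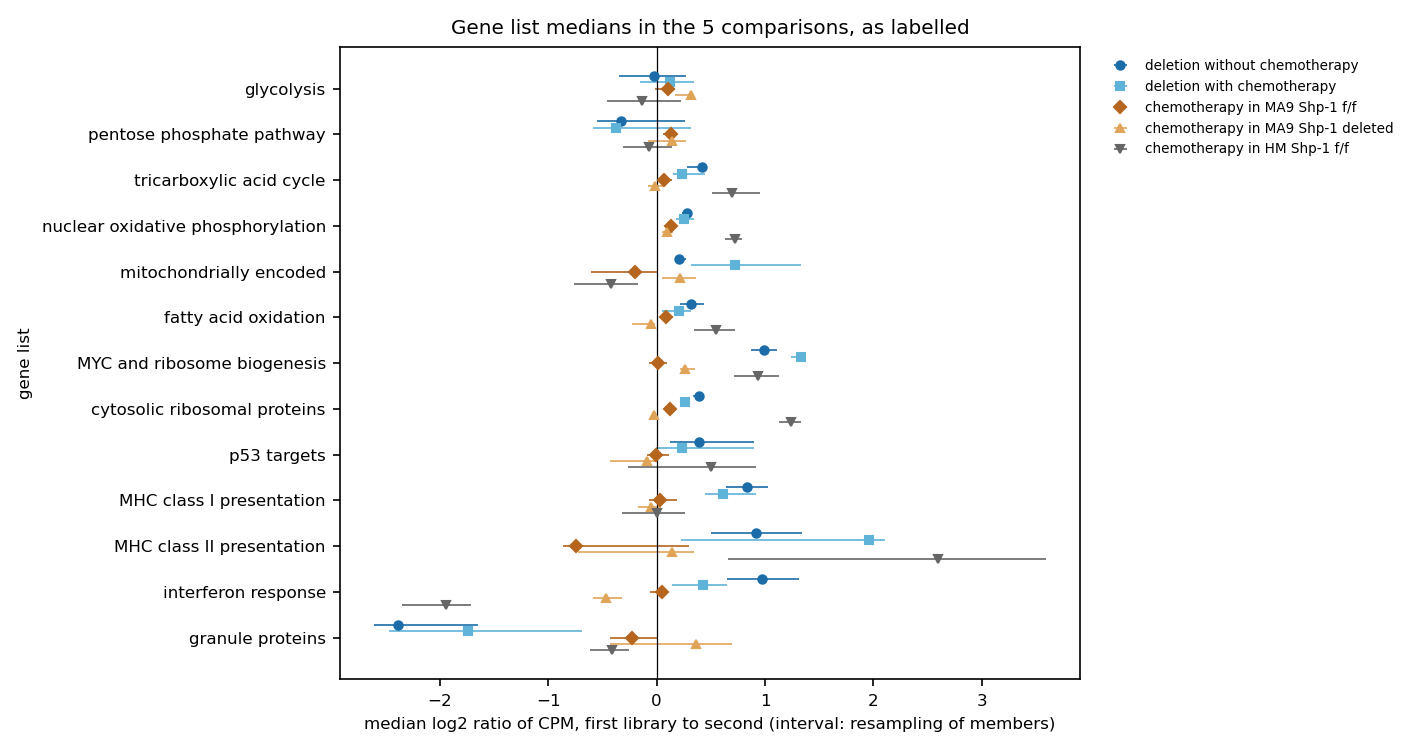
Median log2 ratio of CPM over the members of 13 gene lists in each of the 5 comparisons as labelled (points; bars, 95% resampling of members). Ribosome biogenesis medians were 0.99, 1.34 and 0.93 in the PBS, AraC + Dox and HM pairs (HM -0.037 with all deposited barcodes), and granule protein medians -2.38 and -1.74 in the PBS and AraC + Dox pairs.

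Contrasts that share no library were set against each other across genes, which are not independent replicates. The PBS pair and the AraC + Dox pair had a Pearson correlation of 0.74 and a Spearman correlation of 0.79 over 5886 genes, with 125 genes at least 2-fold higher in both (9.57 expected from the counts alone) and 142 lower in both (9.39 expected). The f/f pair and the Δ/Δ pair, the pairs labelled as chemotherapy, had 0.13 and 0.12 over 5466 genes, with 1 gene higher in both (0.0659 expected) and 19 lower in both (0.525 expected). The Pearson correlation of this last comparison was 0.30 with each cell given equal weight and 0.305 with each cell thinned to 2000 UMIs. The HM pair had a Pearson correlation of 0.50 with the PBS pair and 0.43 with the AraC + Dox pair, against 0.19 with the f/f pair and 0.04 with the Δ/Δ pair. With all deposited barcodes the first of these were 0.262 and 0.184, and with no CPM minimum that with the f/f pair was 0.00279 and that with the Δ/Δ pair -0.079. Its Spearman correlations were 0.55, 0.50, 0.27 and 0.25.

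Whether the AraC + Dox ratios differed with the Shp-1 label was read member by member, as the log2 ratio in the Δ/Δ pair minus that in the f/f pair. Glycolysis was above 0 in 17 of 21 members (median 0.16), ribosome biogenesis in 22 of 24 (0.29), mitochondrially encoded genes in 12 of 13 (0.32) and granule proteins in 15 of 20 (0.41). Interferon response genes were above 0 in 1 of 23 (-0.51), NK cell ligands in 0 of 6 (-0.32), autophagy and lysosome genes in 2 of 22 (-0.20) and fatty acid oxidation in 4 of 20 (-0.16). Oxidative phosphorylation was above 0 in 31 of 73 (-0.05, 0.04 with median-of-ratios scaling and -0.13 with each cell given equal weight), and glycolysis was 0.25 with that scaling. Median-of-ratios scaling shifts all ratios by 0.0985 in the Δ/Δ pair and by 0.0075 in the f/f pair, so every difference above moves up with it. These differences were not tested.

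The last comparison set stem and progenitor-like cells against neutrophil-like and monocyte-like cells, including immature and dividing ones, within each library, where the label in doubt plays no part. In HM the progenitor-like class was cluster 15, with 14 stem and progenitor markers and also 8 of plasmacytoid dendritic cells. In MA9 its cluster 6 had 9 and also 5 of mast cells and basophils. The median of glycolysis genes was lower in progenitor-like cells in 5 of 5 libraries, by a mean of -0.36 on the log2 scale (SD 0.07, n = 5 libraries). Single members need not follow it. Among those of 1 sign in every library, Slc16a3 was at -1.89 (SD 1.16), Eno1 at -1.03 (SD 0.37) and Gpi1 at -0.62 (SD 0.33). The pentose phosphate pathway was lower in 5 of 5 (-0.51, SD 0.11), with G6pdx, its entry enzyme, at -1.48 (SD 0.68). Higher in 5 of 5 were mitochondrially encoded genes (0.48, SD 0.37), fatty acid oxidation (0.34, SD 0.47; Hadh 0.89) and MHC class I (0.51, SD 0.26; Tap2 1.05). So were NK cell ligands (0.91, SD 0.55, 3 to 5 members; Cd48 1.16) and the BCL2 family (0.37, SD 0.27; Bcl2 2.37, SD 1.11). Fatty acid and cholesterol synthesis (0.29, SD 0.16; Scd2 1.15) and MLL and HOX leukaemia genes (0.35, SD 0.33) were also higher in 5 of 5. Granule proteins were lower (-5.60, SD 1.73). The leukaemia and granule lists rest on 8 to 16 and on 5 members that are not markers. Related genes named the compared classes, so the signs of these lists are no separate evidence. Nuclear oxidative phosphorylation was higher in 3 of 5 (0.19, SD 0.52), the tricarboxylic acid cycle in 4 of 5 (0.29) and S phase in 2 of 5 (-0.17). Pfkp was higher in 2 of 5 (-0.10, SD 0.61) and Ptpn6 in 3 of 5 (-0.05, SD 0.52).

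A two-sided exact sign-flip test over the 5 libraries cannot give a p below 0.0625. The 10 lists of 28 with a common sign had this p, Benjamini-Hochberg adjusted to 0.175, so none passed a threshold of 0.05. Oxidative phosphorylation had an exact p of 0.688 (adjusted 0.910 over the 28 lists, 3 of 5 libraries above 0). Scaled with TMM factors, 10 lists changed sign, among them fatty acid and cholesterol synthesis (-0.08) and oxidative phosphorylation (-0.07), and without the HM library oxidative phosphorylation was -0.03. At a Leiden resolution of 0.5 oxidative phosphorylation was -0.15 and the tricarboxylic acid cycle -0.038. Without that library fatty acid oxidation was 0.14, the tricarboxylic acid cycle 0.068 and S phase -0.55, and S phase was 0.081 without the library labelled MA9 f/f AraC + Dox. Progenitor-like and the other cells differed in depth, by medians of 31363 and 7095 UMIs in the HM library and 4500 and 8024 in that labelled MA9 f/f AraC + Dox, and the HM PBS library held too few progenitor-like cells (12) to be used.

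**Figure D5:**
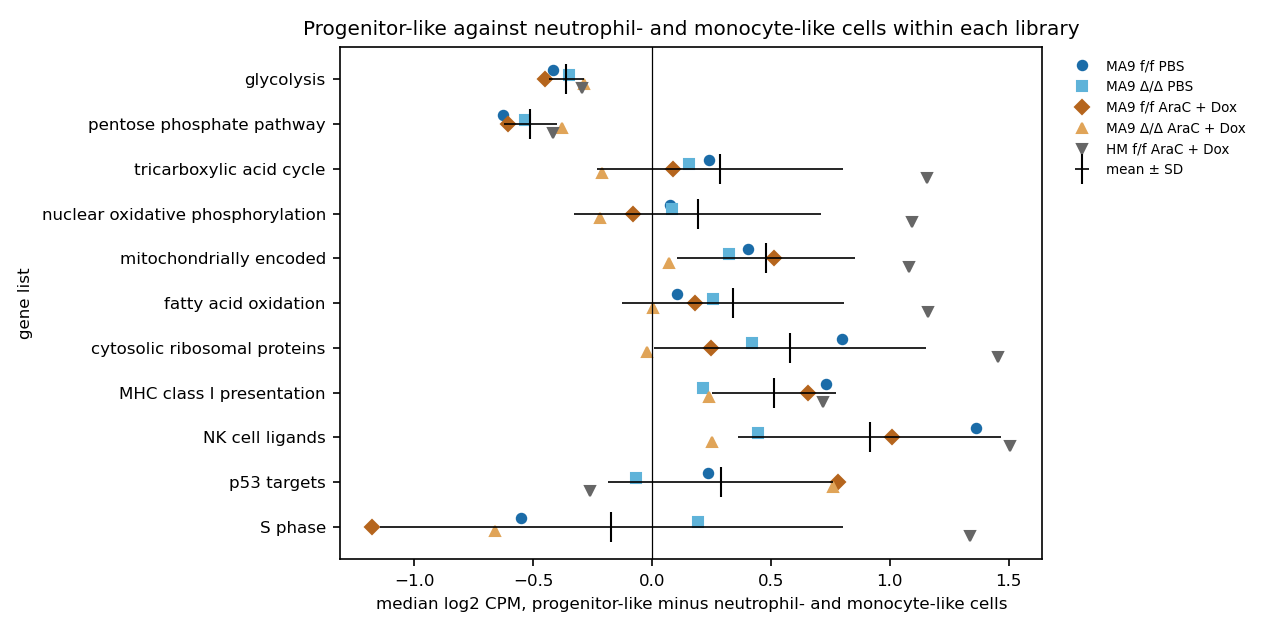
Difference in log2 CPM between stem and progenitor-like cells and neutrophil-like and monocyte-like cells within each library (coloured points, median over the members of a list; black marks, mean and SD over 5 libraries). Glycolysis lay between -0.45 and -0.29 and the pentose phosphate pathway below 0 in the 5 libraries, while oxidative phosphorylation lay on both sides of 0.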

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

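The tests of lower Ptpn6 under AraC + Dox in both models, of broken cells or debris, of fewer leukaemia-derived cells in all and in deep cells, and of shallow barcodes in B cell-like and T cell-like cells apart were chosen only after the result was seen, and the other tests before. Ptpn6 went against the labels of 2 MA9 libraries, standing at 172 CPM in that labelled Δ/Δ PBS and at 57.7 CPM in that labelled f/f AraC + Dox. A different mix of cell classes would bring the ratios within classes near 0, but the median over 4 classes was -1.69 (from -1.84 in monocyte-like to -0.18 in T cell-like cells), which argues against it. Lower Ptpn6 under AraC + Dox in both models is argued against by the HM log2 ratio of -0.25 (-0.33 to -0.18). An exchange of these 2 labels remains a candidate explanation. The HM contrast correlated across genes by a mean of 0.465 with the pairs labelled as deletion. With those labelled as chemotherapy the mean was 0.115, a difference of 0.35. A value well below 0 had been taken beforehand as speaking for the labels, which assumes that AraC + Dox acts alike in both models. With all deposited barcodes kept these were 0.223, 0.0790 and 0.144, so the size of the difference depends on the cell filter. T cell-like shares were 9.42, 4.97 and 4.40 times as high in the HM, PBS and AraC + Dox pairs. They were 1.39-fold and 1.57-fold lower in the f/f and Δ/Δ pairs, and neutrophil-like shares fell in every pair. Genes at least 2-fold higher numbered 22 and 47 in the f/f and Δ/Δ pairs, against 235 and 333 in the PBS and AraC + Dox pairs. A like cell mix or fewer changed genes could give the same order, so the correlations cannot decide between the labels. Medians of p53 targets, read afterwards, were 0.39, 0.24 and 0.50 in the PBS, AraC + Dox and HM pairs. They were -0.01 and -0.09 in the f/f and Δ/Δ pairs. The HM value did not hold with all deposited barcodes kept, and cell mix may bear on this list, so these medians cannot decide either. The names of the deposited files of the 2 libraries in doubt, read as abbreviations, also go against their labels, and groups were taken from the labels. A drug effect on Ptpn6 in MA9 alone, together with a 3′ tag outside the deleted part, also stays open, and no other biological explanation of the order was tested.

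In the HM PBS library, a sample far from the others, 74.7% of barcodes lay over the mitochondrial limit, 9316 barcodes that the comparisons do not use. Broken cells or debris may account for them. Their median depth was 0.291 times that of the kept cells (1158.5 against 3975 UMIs), but only the kept cells had to hold at least 500 genes. These barcodes, with no such minimum, had a median of 489.5 genes. The filter itself thus lowers this ratio, which cannot decide the matter. A class of cells with a high mitochondrial share may do so too: across 6005 genes their other UMIs correlated by only 0.761 with those of the kept cells, with S100a8 at 17371 against 117589 CPM, Mpo higher by 0.68 on the log2 scale and Elane, of the same granules, lower by 0.97. Both explanations stay open, and Pfkp was higher by 1.21 in these barcodes than in the kept cells. No explanation from the groups of the design was tested for these barcodes.

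B cell-like and T cell-like cells were more frequent in both MA9 libraries labelled Δ/Δ, by 10.1-fold and 4.97-fold in the PBS pair and by 11.8-fold and 4.40-fold in the AraC + Dox pair. The B cell-like class is not the same clusters in each library: cluster 16 held 9 and 11 cells of the libraries labelled f/f and 392 and 434 of those labelled Δ/Δ, and cluster 28 held 26 and 26 against 0 and 0. Shallow barcodes passing the filter are argued against for T cell-like cells, whose share among cells of 2000 or more UMIs was 4.78 (3.55 to 6.54) and 4.79 times as high. For B cell-like cells, with median depths of 1583 and 1260.5 UMIs in the libraries labelled Δ/Δ, the fold fell to 2.97 in the PBS pair and 2.05 (1.01 to 4.35) in the AraC + Dox pair, which leaves this open. Both classes together gave 4.29 and 4.03, but T cell-like cells make up most of these, so that value does not settle the matter for B cell-like cells. A loss of leukaemia cells that raises every other class alike stays open. The log2 ratios of 4 such classes in the PBS pair spread over 1.82, from 1.52 for plasma cell-like to 3.34 for B cell-like cells, but that spread rests on the B cell-like fold. Among cells of 2000 or more UMIs it was 0.68, from 1.57 for B cell-like to 2.26 for T cell-like cells. An effect of the Shp-1 label, or of AraC + Dox if the labels in doubt were exchanged, stays open and was not tested. In the HM pair the share of both classes in deep cells was 19.5% with AraC + Dox and 1.41% with PBS, where the filter passed only 22.1% of barcodes.

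Further differences between contrasts stood out because the median of a list went one way in 1 pair of libraries and the opposite way in another, while single members need not. Haemoglobin genes had a median of -1.83 in the f/f pair and 3.73 in the Δ/Δ pair, a gap of -5.56, and the difference was not tested. Erythroid-like shares do not settle it, since they depend on the clustering: with AraC + Dox and PBS they were 2.69% and 0.134% in the f/f pair and 0.0331% and 0.0330% in the Δ/Δ pair, but 0.296% and 0.401%, and 0.441% and 0.143%, at a Leiden resolution of 0.5. At a resolution of 1 the haemoglobin genes alone named that class, so its share is no separate evidence. Against the HM pair (-6.08) the Δ/Δ pair lay 9.82 higher in the same genes, and the difference was not tested. These genes summed to only 5.25 CPM in the library labelled Δ/Δ PBS, against 69.7 CPM in that labelled Δ/Δ AraC + Dox. The sums were 1074 and 315 CPM in those labelled f/f PBS and f/f AraC + Dox. The 3.73 is thus a ratio to 1 library with little haemoglobin RNA. MHC class II genes lay -3.34 apart between the f/f pair (-0.75) and the HM pair (2.59), and the difference was not tested. Granule proteins lay 0.78 apart between the Δ/Δ pair (0.37) and the HM pair (-0.42), and the difference was not tested. With all deposited barcodes kept the HM median was 0.21, in the direction of the Δ/Δ pair, and with each cell given equal weight the Δ/Δ median was -0.083.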

How the results depend on the processing

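The alternatives to the correlations, to the Δ/Δ pair minus the f/f pair and to the pair compared were chosen after seeing the data, and the others were planned. Of the results that answer a comparison, 400 values under alternatives stayed within the first interval (counts of genes within 1.5 times, correlations near the first value, progenitor-like differences with the same sign), 122 moved further, 26 turned, and 14 counts rose and 12 fell by more than 1.5 times. Of named genes and lists 1273 stayed, 298 moved and 12 turned. A ratio or median turned where its first interval excluded 0 and its new value lay on the other side of 0, and a correlation or a progenitor-like difference where its sign changed. Counting also values whose first interval held 0, such as glycolysis and Pfkp in the HM pair, 31 and 83 lay on the other side of 0. The planned separation of classes gave no value where a class was not named, as for conventional dendritic cell-like cells at the other resolutions. No paired analysis was possible because each group held 1 library and the labels name no animal. Depth limits the ratios within small classes, such as T cell-like Ptpn6 in the f/f pair (51 and 64 cells). Each value below stands in place of the first one computed, which the report gives where it describes that result, and except where a higher or no CPM minimum changes the number of genes compared, the cause was not tested.

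In the 1 pair of MA9 libraries whose labels Ptpn6 does not go against, the library labelled Δ/Δ AraC + Dox against that labelled f/f PBS, deletion and chemotherapy differ together. Set in place of each MA9 pair it gave log2 ratios of -2.10 for Ptpn6 and 1.0 for Pfkp, medians of 0.38 for oxidative phosphorylation and 0.25 for glycolysis, and 310 genes higher and 339 lower of 6103.

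With median-of-ratios size factors, the genes at least 2-fold higher numbered 140 in the PBS pair. The Ptpn6 log2 ratio was -0.29 in the PBS pair, -0.49 in the AraC + Dox pair, -1.88 in the Δ/Δ pair and -0.33 in the HM pair. The Pfkp log2 ratio was 0.34 in the PBS pair, 0.60 in the AraC + Dox pair and 0.59 in the Δ/Δ pair. The glycolysis median was 0.41 in the Δ/Δ pair. The oxidative phosphorylation median was 0.11 in the PBS pair, 0.17 in the AraC + Dox pair and 0.19 in the Δ/Δ pair. The Δ/Δ pair minus the f/f pair was 0.25 for glycolysis and 0.040 for oxidative phosphorylation. The medians that turned were -0.029 for AMPK and mTORC1 regulators in the PBS pair, -0.071 for sex-linked genes in the PBS pair, 0.049 for fatty acid oxidation in the Δ/Δ pair and 0.023 for AMPK and mTORC1 regulators in the Δ/Δ pair. With TMM factors, the genes at least 2-fold higher numbered 142 in the PBS pair. The Ptpn6 log2 ratio was -0.28 in the PBS pair, -0.48 in the AraC + Dox pair and -1.90 in the Δ/Δ pair. The Pfkp log2 ratio was 0.34 in the PBS pair, 0.62 in the AraC + Dox pair and 0.57 in the Δ/Δ pair. The glycolysis median was 0.40 in the Δ/Δ pair. The oxidative phosphorylation median was 0.11 in the PBS pair and 0.17 in the Δ/Δ pair. The medians that turned were -0.024 for AMPK and mTORC1 regulators in the PBS pair, -0.066 for sex-linked genes in the PBS pair, 0.032 for fatty acid oxidation in the Δ/Δ pair and 0.0066 for AMPK and mTORC1 regulators in the Δ/Δ pair. The progenitor-like minus neutrophil- and monocyte-like difference changed sign to -0.071 for oxidative phosphorylation, -0.084 for fatty acid and cholesterol synthesis, -0.23 for AMPK and mTORC1 regulators, -0.22 for antioxidant response, -0.041 for p53 targets, -0.22 for drug transport and nucleoside metabolism, -0.19 for interferon response, -0.41 for NF-kB and inflammatory cytokines, -0.11 for JAK-STAT feedback and -0.032 for immediate early and heat shock. With each cell given equal weight, the Ptpn6 log2 ratio was -0.037 in the PBS pair, 0.026 in the AraC + Dox pair, -1.78 in the f/f pair, -1.72 in the Δ/Δ pair and -0.17 in the HM pair. The Pfkp log2 ratio was 0.60 in the Δ/Δ pair and 0.013 in the HM pair. The oxidative phosphorylation median was 0.17 in the AraC + Dox pair and 0.20 in the f/f pair. The correlation across genes was 0.30 between the f/f pair and the Δ/Δ pair. The Δ/Δ pair minus the f/f pair was -0.13 for oxidative phosphorylation. The median that turned was 0.085 for NF-kB and inflammatory cytokines in the AraC + Dox pair. With each cell thinned to 2000 UMIs, the Ptpn6 log2 ratio was -0.15 in the PBS pair, -1.79 in the f/f pair, -2.07 in the Δ/Δ pair and -0.074 in the HM pair. The Pfkp log2 ratio was 0.30 in the PBS pair, 0.78 in the AraC + Dox pair and 0.72 in the Δ/Δ pair. The oxidative phosphorylation median was 0.20 in the f/f pair. The correlation across genes was 0.305 between the f/f pair and the Δ/Δ pair. The median that turned was 0.0019 for fatty acid oxidation in the Δ/Δ pair. The progenitor-like minus neutrophil- and monocyte-like difference changed sign to 0.065 for hypoxia response, -0.029 for interferon response and -0.030 for NF-kB and inflammatory cytokines. With all deposited barcodes kept, the Ptpn6 log2 ratio was 0.16 in the HM pair. The Pfkp log2 ratio was -0.56 in the HM pair. The glycolysis median was 0.36 in the HM pair. The oxidative phosphorylation median was 1.17 in the HM pair. The correlation across genes was 0.262 between the PBS pair and the HM pair and 0.184 between the AraC + Dox pair and the HM pair. The medians that turned were -0.037 for MYC and ribosome biogenesis in the HM pair and 0.21 for granule proteins in the HM pair. With a stricter cell filter (1000 genes, 5.0% mitochondrial UMIs), the oxidative phosphorylation median was 0.54 in the HM pair. With at least 50 CPM asked in either library, the counts of genes at least 2-fold higher and lower were 125 and 133 in the PBS pair, 193 and 159 in the AraC + Dox pair, 9 and 26 in the f/f pair, 23 and 45 in the Δ/Δ pair and 363 and 295 in the HM pair. The correlation across genes was 0.167 between the Δ/Δ pair and the HM pair. With no CPM minimum (10 UMIs over both libraries), the counts of genes at least 2-fold higher and lower were 2037 and 983 in the PBS pair, 2325 and 1167 in the AraC + Dox pair, 445 and 917 in the f/f pair, 773 and 1181 in the Δ/Δ pair and 2634 and 1626 in the HM pair. The correlation across genes was 0.589 between the PBS pair and the AraC + Dox pair, 0.326 between the AraC + Dox pair and the HM pair, 0.00279 between the f/f pair and the HM pair and -0.0788 between the Δ/Δ pair and the HM pair.

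At a Leiden resolution of 0.5, erythroid-like cells were 0.401% of MA9 f/f PBS, 0.143% of MA9 Δ/Δ PBS, 0.296% of MA9 f/f AraC + Dox and 0.441% of MA9 Δ/Δ AraC + Dox. Granulocyte-monocyte progenitor-like cells were 10.1% of MA9 f/f PBS, 6.59% of MA9 Δ/Δ PBS, 13.9% of MA9 f/f AraC + Dox, 1.89% of HM PBS and 10.7% of HM AraC + Dox. Macrophage-like cells were 0.778% of MA9 f/f PBS, 1.70% of MA9 Δ/Δ PBS, 0.570% of MA9 f/f AraC + Dox and 1.41% of MA9 Δ/Δ AraC + Dox. Monocyte-like cells were 15.4% of MA9 f/f PBS, 15.5% of MA9 Δ/Δ PBS, 23.4% of MA9 Δ/Δ AraC + Dox, 9.55% of HM PBS and 4.92% of HM AraC + Dox. Cells of unnamed clusters were 5.63% of MA9 f/f PBS, 15.8% of MA9 Δ/Δ PBS and 8.30% of MA9 f/f AraC + Dox. Stem and progenitor-like cells were 40.2% of MA9 Δ/Δ PBS and 5.26% of MA9 Δ/Δ AraC + Dox. Plasma cell-like cells were 0.148% of HM PBS and 0.805% of HM AraC + Dox. Signs of progenitor-like minus neutrophil- and monocyte-like differences changed to -0.038 for tricarboxylic acid cycle, -0.15 for oxidative phosphorylation, 0.070 for hypoxia response, -0.14 for antioxidant response, -0.33 for DNA repair, -0.070 for MYC and ribosome biogenesis, 0.33 for immune inhibitory ligands and 0.28 for autophagy and lysosome. At a Leiden resolution of 1.5, granulocyte-monocyte progenitor-like cells were 8.06% of MA9 f/f PBS, 11.2% of MA9 f/f AraC + Dox and 25.6% of MA9 Δ/Δ AraC + Dox. Neutrophil-like cells were 46.9% of MA9 f/f PBS, 39.6% of MA9 f/f AraC + Dox and 7.69% of MA9 Δ/Δ AraC + Dox. Stem and progenitor-like cells were 11.3% of MA9 f/f PBS, 24.6% of MA9 Δ/Δ PBS and 4.33% of MA9 Δ/Δ AraC + Dox. Cells of unnamed clusters were 18.6% of MA9 f/f PBS, 43.3% of MA9 Δ/Δ PBS, 18.6% of MA9 f/f AraC + Dox, 28.8% of MA9 Δ/Δ AraC + Dox, 2.37% of HM PBS and 6.73% of HM AraC + Dox. Monocyte-like cells were 5.29% of HM PBS and 4.59% of HM AraC + Dox. Signs of progenitor-like minus neutrophil- and monocyte-like differences changed to 0.0016 for S phase and -0.0031 for NF-kB and inflammatory cytokines. With Scrublet doublets kept, erythroid-like cells were 0.580% of MA9 f/f PBS, 0.254% of MA9 Δ/Δ PBS, 4.28% of MA9 f/f AraC + Dox and 0.455% of MA9 Δ/Δ AraC + Dox. Macrophage-like cells were 0.685% of MA9 f/f PBS, 1.29% of MA9 Δ/Δ PBS, 0.451% of MA9 f/f AraC + Dox and 1.249% of MA9 Δ/Δ AraC + Dox. Stem and progenitor-like cells were 11.2% of MA9 f/f PBS. Monocyte-like cells were 6.90% of MA9 Δ/Δ PBS and 23.9% of MA9 f/f AraC + Dox. Cells of unnamed clusters were 46.7% of MA9 Δ/Δ PBS, 29.8% of MA9 Δ/Δ AraC + Dox and 0.145% of HM PBS. T cell-like cells were 21.8% of HM AraC + Dox. Plasma cell-like cells were 1.13% of HM AraC + Dox.

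Leaving out each library in turn, the progenitor-like minus neutrophil- and monocyte-like difference ranged from -0.033 to 0.22 for AMPK and mTORC1 regulators, from -0.092 to 0.44 for DNA repair, from -0.23 to 0.42 for NF-kB and inflammatory cytokines, from -0.55 to 0.081 for S phase, from -0.16 to 0.14 for autophagy and lysosome, from -0.024 to 0.17 for drug transport and nucleoside metabolism, from -0.20 to 0.057 for hypoxia response, from -0.24 to 0.54 for interferon response and from -0.034 to 0.29 for oxidative phosphorylation. The range was 0.068 to 0.41 for the tricarboxylic acid cycle and 0.14 to 0.43 for fatty acid oxidation, with the lower end without the HM library. Glycolysis stayed between -0.38 and -0.34 and the pentose phosphate pathway between -0.55 and -0.48.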

Other observations

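No test in this part was planned: the values were read after the results had been seen, and all are given as values. Interferon response genes stood apart in neutrophil-like cells of MA9. In the PBS pair 12 of 12 measured members were higher in the library labelled Δ/Δ (median log2 ratio 1.49), and in the AraC + Dox pair 20 of 20 (3.11), while monocyte-like cells, most of them in different clusters too, had medians of 0.07 and -0.56. Of these neutrophil-like cells 660 of 1036 in the library labelled Δ/Δ PBS lay in cluster 12, which held 363 of 4506 in that labelled f/f PBS. Abcb1b, a pump that exports doxorubicin, had a log2 ratio of 1.70 (1.55 to 1.85) in the PBS pair, and Pim1, a kinase induced by cytokine signals, 2.61 (2.55 to 2.67) there and 1.57 (1.53 to 1.61) in the AraC + Dox pair. DNA repair genes were higher in 10 of 20 members and lower in 0 in the PBS pair (0.31) and higher in 15 and lower in 2 of 20 in the AraC + Dox pair (0.41), with Parp1 at 1.01 and 0.92. Inflammatory cytokine and NF-kB genes were higher in 13 and lower in 9 of 25 in the HM pair (0.75). The chemokine Ccl5 was at 3.22 (3.06 to 3.38) and Osm at -2.20. Ccl5 is a top gene of T cell-like cluster 2, with 713 cells with AraC + Dox and 21 with PBS. Osm is a top gene of neutrophil-like cluster 0, with 11 and 1083 cells.

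Xist, the RNA that silences 1 X chromosome in female cells, was measured by class. In B cell-like cells it reached 558 CPM (502 to 618) in the library labelled MA9 Δ/Δ PBS and 816 CPM (745 to 893) in that labelled MA9 Δ/Δ AraC + Dox, against 75.6 CPM (30.4 to 156) and 45.1 CPM (12.3 to 115) in those labelled f/f PBS and f/f AraC + Dox. In stem and progenitor-like cells of the same libraries it was 0.186 CPM (4 UMIs) and 0 CPM, with an upper limit of 1.99. T cell-like cells of the MA9 libraries held between 13.1 and 79.2 CPM. In HM it was 0 CPM in B cell-like cells with AraC + Dox, with an upper limit of 11.6. Ptpn6 in the Δ/Δ pair stood at 361 and 385 CPM in B cell-like cells and at 118 and 119 CPM in T cell-like cells, the classes in which it was not detectably lower. Ddx3y, on the Y chromosome, lay between 38.3 and 50.7 CPM over all kept cells of the 6 libraries. In B cell-like cells it was 62.5 and 55.0 CPM in the MA9 libraries labelled Δ/Δ PBS and Δ/Δ AraC + Dox, and 162 and 90.2 CPM in those labelled f/f PBS and f/f AraC + Dox.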
